A study of Rattus norvegicus with 71 samples.

How the data were processed

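Total RNA of arteries of Brown Norway (BN) and Fischer344 × Brown Norway (FBN) rats was measured on 71 Affymetrix rat arrays. Per the labels the RNA was purified with a column kit for fibrous tissue and labelled with biotin from less than 1 ug. The labels also cite a collateral artery model with an adjacent arterial occlusion, without saying which vessels came from it. The deposited values are intensity, the MAS5 signal on a linear scale, for 31099 probe sets. Per the submitters' processing notes they were made with GCOS and MAS5, and the versions are not given in the sources used here. In every array the mean after leaving out the lowest and highest 2% of probe sets was 1000.3 to 1000.4, so each array had been scaled to the same trimmed mean. Array medians ranged from 278.9 to 346.4, and signals from 0.136 to 134703, with 0 values at or below 0. Detection calls and scan dates were not in the data used here. All columns belonged to a labelled sample.

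Signals were log2-transformed without an offset. The 57 control probe sets were left out, and 16717 probe sets were tested, those whose mean log2 signal over the aorta arrays or over the mesenteric arrays reached the median over probe sets of the mean over all arrays (8.19, a signal of 292.4). The number of arrays, 5 or 6 per group, limits the precision. Gene symbols came from the platform's gene table, which lists 1 symbol for 20832 probe sets, several for 436 and none for 9780. Of these, 20764 had a gene identifier found in a current reference table, and 0 symbols changed by it. Among tested probe sets 12889 had 1 symbol, for 9785 genes.

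Groups were fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0) as 6 group means per vessel, and as 12 group means over all arrays for comparisons between vessels. Moderated two-sided tests used eBayes with a trend and robust estimates. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, and calls were made at 0.05. They measure the spread between arrays, since the labels do not state whether each array is a separate animal. There were 19 planned comparisons, 7 of them main ones. After the data were seen 14 more were fitted. Of these, 3 are described: the age change averaged over strains in each vessel, and the strain difference at 6 and 15 months in mesenteric artery. The other 11, within single ages or strains, are not described.

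Gene groups were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists within a comparison. Of 38 lists, 33 had at least 4 tested members. The lists cover cell types of the vessel wall and of fat, muscle and nerve, and functions such as matrix, inflammation and metabolism. The T and NK cell (3 tested members), B and plasma cell (2), mast cell (3), erythrocyte (3) and exocrine pancreas and gut (0) lists were too small to test. Many list genes are also expressed by more than 1 cell type of a vessel wall and its surrounding tissue. Each gene entered a list by its probe set with the highest mean signal, and a score is the mean log2 signal of a list.

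The comparisons, the lists, the alternatives below not described as added, and the rule for named genes were fixed before the data were examined. In main comparisons the rule names the 10 genes with the largest rise and 10 with the largest fall among those called with 1 symbol. In other comparisons it names 3 in each direction, and in each list up to 4 members with the smallest p. It held for added comparisons too. Clock genes beyond 4, Col1a1, Esm1, Srpx2 and Uchl1 in both vessels, Cpeb1 at 15 months in BN mesenteric artery, and genes named with a covariate, were chosen after their values were seen. Array quality was tested by exact permutation tests on the ratio of end to start signal of Gapdh and Actb and on array medians (54 tests, 0 passing). Their smallest possible p, 0.00216 unadjusted, was reached for Gapdh in mesenteric arrays labelled BN at 15 against 6 and 24 against 15 months. Spike-in tests were added later (36 tests, 13 passing). Correlations used 100000 permutations.

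Alternatives to these choices were quantile normalization, an offset of 81.3 before the log2, no filter, a stricter filter at the 75th percentile (1127.9), eBayes without trend and robust estimates, array weights, 1 fit of all 71 arrays, tissue mass as a covariate, and leaving out each array in turn. Added after the data were seen were the poly-A spike-in signal as a covariate, the brown adipocyte score as a covariate in aorta, a fit of each strain and vessel alone, exchanged strain labels of 24-month mesenteric arrays, and other choices of strain markers. Up to 100 splits of the arrays per comparison, the real one included, were fitted as the real groups were. Tests on simulated data had 200 changed probe sets. Of changes of 1 log2 unit 66% were recovered in BN aorta, 68% in FBN aorta and 86% in each mesenteric comparison. For 2 units it was 92% to 98%. Of calls 4.1% to 6.8% were false, but splits of real FBN aorta arrays called up to 8201. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.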

Results

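RNA from aorta (35 arrays) and mesenteric artery (36) of Brown Norway (BN) and Fischer344 × Brown Norway (FBN) hybrid rats was measured. The rats were 6, 15 or 24 months old, per the labels. Each of the 12 groups held 6 arrays, except BN aorta at 15 months with 5, and this number limited the precision of every value. Changes are given as log2 differences ± standard error, and signals as mean ± SD. Calls rest on limma's two-sided moderated test at an adjusted p of 0.05 over 16717 probe sets. No offset was added before the log2, so the size of a change from near background depends on that choice. Genes said to rise, fall, or be higher or lower passed this test where no p is given.

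Marker genes of fat cells differed between the vessels and between the strains' aortas. The brown adipocyte thermogenic gene Ucp1 had a signal of 75495 ± 25600 in aorta arrays (n = 35) and of 46.8 ± 38.7 in mesenteric arrays (n = 36). The brown adipocyte score, a mean log2 signal of listed marker genes, was 13.70 ± 0.18 in BN aorta and 12.68 ± 1.1 in FBN aorta at 6 months (n = 6 each). Tissue mass at that age was 25.87 ± 3.5 mg and 18.62 ± 8.9 mg. The lowest correlation between arrays of 1 group, across probe sets, was 0.943 in BN aorta, 0.892 in mesenteric artery and 0.745 in FBN aorta.

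Strain marker genes did not follow the deposited strain labels in the 24-month mesenteric arrays. A score of 24 markers, chosen from 6- and 15-month aorta arrays, averaged -0.52 ± 0.081 in BN and 0.95 ± 0.071 in FBN mesenteric arrays at 6 months (n = 6 each). At 24 months it averaged 0.99 ± 0.032 in mesenteric arrays labelled BN and -0.58 ± 0.057 in those labelled FBN (n = 6 each). All 12 of these arrays lay on the other strain's side, and 0 of the 36 other arrays that had no part in choosing the markers did. The markers were chosen after the data were seen, and for a wider choice of 108 markers this count was 6 of 12 with the aorta's midpoint and 12 of 12 with the mesenteric midpoint. Strain names of 24-month mesenteric arrays are therefore given below as labels only.

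**Figure D1:**
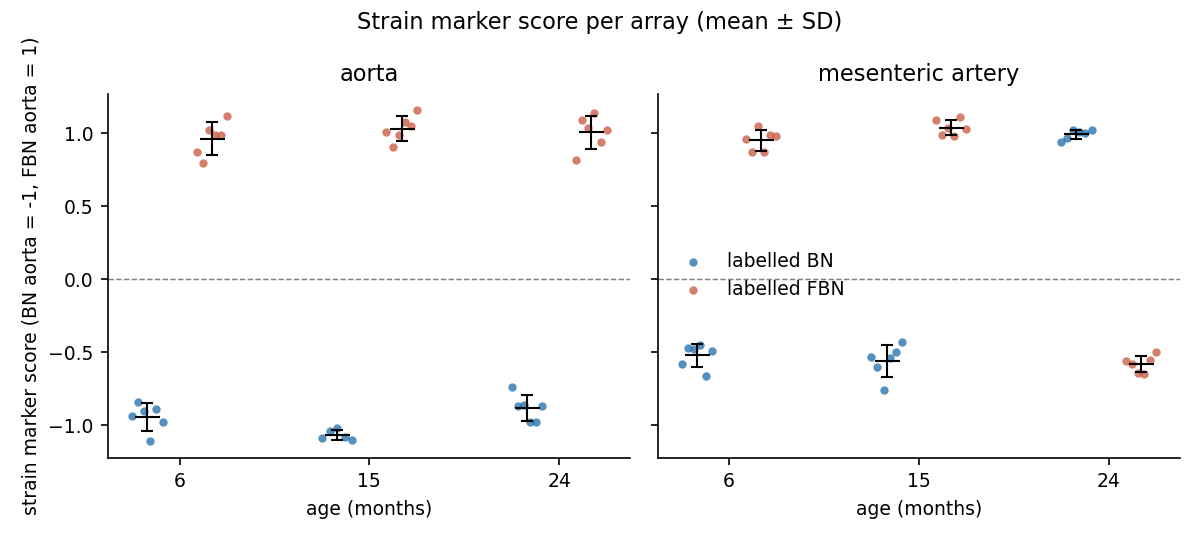
Strain marker score (mean of 24 markers, scaled so that the BN aorta mean is -1 and the FBN aorta mean is 1) of each array by age and vessel, with bars for mean ± SD. In mesenteric artery at 24 months the arrays labelled BN average 0.99 and those labelled FBN average -0.58.

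The first comparison asked, as far as the labels state, what differed between BN aortas of 24 and 6 months (n = 6 each). Cpeb1, which binds messenger RNA tails to control translation, rose 3.64-fold, from 204 ± 64.8 to 724 ± 164 (log2 1.86 ± 0.23, adjusted p = 5.81e-05). Nnat, an imprinted membrane proteolipid gene, rose from 1809 ± 651 to 7748 ± 1670 (2.14 ± 0.29, adjusted p = 8.8e-05). Tfpi, the inhibitor of the tissue factor pathway of coagulation, rose 5.88-fold (2.56 ± 0.38, adjusted p = 0.000236). Inhbb, the activin beta B subunit, rose from 30.2 ± 32.8 to 223 ± 67 (3.43 ± 0.54, adjusted p = 0.000454). Its 6-month signal was near background, and over the alternatives the value ranged from 1.46 to 3.59. Slbp, which binds the end of histone messages, fell by 1.14 ± 0.15 (adjusted p = 7.9e-05), and Slc25a1, the mitochondrial citrate carrier, fell by 1.43 ± 0.34 (adjusted p = 0.0279).

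Other genes higher in 24-month BN aorta included the acute-phase protease inhibitor Serpina3n (1.54, adjusted p = 0.00271), the macrophage glycoprotein Gpnmb (1.44, adjusted p = 0.00241) and the class I histocompatibility gene RT1-CE5 (1.98, adjusted p = 0.0115). The membrane dipeptidase Dpep1 (2.17, adjusted p = 0.0212), the kinase anchor Sphkap (2.08, adjusted p = 0.0346) and the G-protein subunit Gng2 (2.17, adjusted p = 0.0493) rose as well, shrinking to 1.01 for Dpep1 and 1.18 for Gng2 over the alternatives. Lower genes included fructokinase Khk (-1.37), the dicarboxylate carrier Slc25a10 (-1.16), phosphofructokinase Pfkp (-1.16), acetoacetyl-CoA synthetase Aacs (-1.18) and the fatty acid binding gene Fabp5 (-1.31). The kinase Pim1 (-1.75), the lysosomal transporter Atp13a2 (-1.29) and the uncharacterized LOC102548586 (-1.59) were also lower. No other probe set of Gng2, Dpep1 or Slc25a10 passed. In all 20 named genes every 24-month array lay beyond the 6-month mean.

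Of 14 interferon-stimulated genes in BN aorta, 4 rose and 0 fell, with 6 higher when adjusted over the list alone. Irf7, an interferon regulator, rose by 1.19 ± 0.18 (adjusted p = 0.000236) and Isg15, a ubiquitin-like protein, by 1.20 ± 0.21 (adjusted p = 0.0019). The list stood higher in camera (adjusted p = 3.4e-09), and with adjusted p = 0.0474 with an estimated correlation. Of 13 cholesterol synthesis genes 0 rose and 3 fell, 7 when adjusted over the list alone, among them farnesyl diphosphate synthase Fdps (-0.95, adjusted p = 0.0019) and Idi1 (-0.97, adjusted p = 0.00697), an isomerase of that pathway. Camera placed this list lower (adjusted p = 2.26e-10, and 0.00127 with an estimated correlation). Of 12 inflammatory genes 2 rose, the leukocyte adhesion gene Icam1 (1.37, adjusted p = 0.00751) and the chemokine Ccl5 (0.96, adjusted p = 0.039), with 5 adjusted over the list alone. Camera placed it higher (adjusted p = 0.00311), but 0.233 with an estimated correlation. None of 15 macrophage genes and none of 9 calcification genes passed, although 4 and 5 rose when adjusted over the list alone. Camera gave adjusted p = 1.14e-06 and 0.000282 for these, and 0.454 and 0.227 with an estimated correlation.

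In BN aorta 112 probe sets rose and 98 fell between 6 and 24 months, for 92 and 74 genes. The calls of Gng2, Fabp5, LOC102548586, Atp13a2, Serpina3n, Khk and Ccl5 ended under at least 1 alternative processing, and those of Sphkap, Pim1, Slc25a1, Aacs, Pfkp and Dpep1 when a single array was left out.

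Between 6 and 15 months in BN aorta (n = 6 and 5) 36 probe sets rose and 75 fell. Inhbb was already higher at 15 months (2.57 ± 0.56, adjusted p = 0.02), as was Cpeb1 (1.05 ± 0.24, adjusted p = 0.0283) and the immune regulator Tnfaip8l2 (1.20, adjusted p = 0.0398). Peli2, a ubiquitin ligase of Toll-like receptor signalling, was lower (-1.55), as were the stress kinase Map3k20 (-1.93) and the vesicle tethering gene Vps52 (-1.65). From 15 to 24 months 31 rose and 11 fell. Map3k20 and Vps52 were higher again (2.28, adjusted p = 0.00211, and 2.34, adjusted p = 0.00143), and Tfpi rose by 1.79 ± 0.4 (adjusted p = 0.0422). The histone methyltransferase Kmt5a (-0.91), the phosphatase Pgp (-0.76) and the proteasome regulator Nfe2l1 (-0.52) were lower. Over the alternatives the 15-month values shrank to 0.89 for Inhbb, 0.71 for Tnfaip8l2 and -0.79 for Vps52, and the later rise of Vps52 to 1.28. Poly-A spike-in signals, of a control added before labelling, were higher at 15 than at 6 months by 0.56 log2 and lower at 24 than at 15 by 0.67 (exact permutation tests, two-sided, adjusted p = 0.0142 and 0.00972). Map3k20 had other probe sets that did not pass, and the calls of Inhbb, Cpeb1, Tnfaip8l2 and Vps52 at 15 months, and of Tfpi, Pgp and Nfe2l1 at 24, ended under at least 1 alternative.

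FBN aortas of 24 and 6 months were compared in the same way (n = 6 each). Nnat rose 5.2-fold, from 2080.1 ± 1030 to 10099.8 ± 2150 (2.38 ± 0.29, adjusted p = 2.13e-05). Cpeb1 rose from 230 ± 26.9 to 721 ± 186 (1.62 ± 0.23, adjusted p = 0.000186), Tfpi rose 5.13-fold (2.36 ± 0.38, adjusted p = 0.000851) and RT1-CE5 rose by 1.53 ± 0.25 (adjusted p = 0.000949). Agt, the precursor of angiotensin, fell from 8898 ± 7270 to 1281 ± 1420 (-2.92 ± 0.53, adjusted p = 0.00289). The clock repressor Nfil3 fell by 1.59 ± 0.24 (adjusted p = 0.000334).

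Other genes that rose in FBN aorta were the neuronal synuclein Sncg (1.59, adjusted p = 0.000195), the clock repressor Bhlhe41 (1.46, adjusted p = 0.00534), the sarcomere protein Lrrc39 (3.06, adjusted p = 0.00717), the zinc finger gene Zcchc18 (1.90, adjusted p = 0.0197), the carboxypeptidase-like Cpxm2 (1.78) and the period gene Per3 (2.13). Slc25a1 fell again (-1.53), with the fatty acid transporter Slc27a1 (-1.32) and the acyl-CoA dehydrogenase Acadsb (-1.35). The secretoglobin Scgb1c1 (-3.44), the histamine receptor Hrh3 (-1.75), the zinc finger repressor Zbtb20 (-1.27), the kinase subunit Prkar2a (-1.44) and the mitotic kinase Nek9 (-1.33) were lower. Over the alternatives Lrrc39 shrank to 1.83, Zcchc18 to 0.95, RT1-CE5 to 0.94, Scgb1c1 to -1.91, Slc25a1 to -1.01 and Slc27a1 to -0.73. The brown adipocyte score was 13.77 and 14.13 in 6-month arrays 1 and 2 and 11.62 to 12.92 in the other 4, and without array 1 the calls of Slc25a1, Slc27a1 and Acadsb ended, while with the score as a covariate they passed (-1.33, -1.19 and -1.21). In all 20 genes every 24-month array lay beyond the 6-month mean.

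Of 14 interferon-stimulated genes in FBN aorta 4 rose and 0 fell, 8 when adjusted over the list alone, among them the guanylate-binding Gbp2 (1.02 ± 0.2, adjusted p = 0.00534) and the antiviral Mx1 (1.12 ± 0.28, adjusted p = 0.0396). The interferon-stimulated list stood higher in camera (adjusted p = 2.62e-07, but 0.17 with an estimated correlation). Of 40 ribosomal protein genes 3 rose, Rpl5 (0.39 ± 0.092, adjusted p = 0.0234), Rps24 (0.35, adjusted p = 0.0416) and Rpl3 (0.29, adjusted p = 0.0471), with 23 when adjusted over the list alone. The ribosomal list stood higher in camera (adjusted p = 8.48e-16, but 0.296 with an estimated correlation). Of 16 circadian clock genes 3 rose and 1 fell, Nr1d2 among those higher (1.33, adjusted p = 0.00534), and camera gave adjusted p = 0.187. Ccnd1, the cyclin of early cell cycle entry, rose by 1.38 ± 0.26 (adjusted p = 0.00465) and Fgf1, a fibroblast growth factor, by 1.08 ± 0.18 (adjusted p = 0.000851). No member of the contractile, heat shock, oxidative phosphorylation or skeletal and cardiac muscle lists passed. Camera called these at adjusted p = 0.02, 0.0146, 2.2e-05 and 0.0317, against 0.824, 0.651, 0.824 and 0.671 with an estimated correlation.

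In FBN aorta 124 probe sets rose and 61 fell, for 97 and 48 genes. Spread was shared with BN arrays (SD 0.25, FBN 0.384), and FBN fitted alone gave 23. In 9 of 100 splits of these arrays, the real one included, at least as many probe sets passed, up to 8201. Of 28 genes named here 21 lost the call under an alternative, all but Zcchc18 when FBN was fitted alone. Nnat, Cpeb1, RT1-CE5, Nfil3, Sncg, Lrrc39 and Fgf1 kept it. Between 6 and 15 months Nnat alone passed, rising by 1.77 ± 0.29 (adjusted p = 0.0165). From 15 to 24 months 2 probe sets rose and 33 fell. Prdm2, a histone methyltransferase (0.80), and the intermediate filament Vim (0.36) rose, while Map3k20 (-1.88), the calcium pump Atp2b4 (-1.66) and the cytolinker Dst (-1.57) fell. Prdm2 shrank to 0.53 and Vim to 0.08, and no other probe set of Prdm2, Map3k20 or Dst passed, with 1 or more of each going the other way. Each of these calls, and that of Nnat at 15 months, ended under at least 1 alternative.

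The age changes of the 2 strains' aortas overlapped. BN and FBN aorta shared 37 called probe sets, all in the same direction, where 1.19 were expected for independent lists, and the changes correlated at r = 0.52 across probe sets, which are not independent replicates. The strains' age changes, tested directly, differed for 5 probe sets. In FBN the change was more positive for the membrane coat gene Cav2 (0.96 ± 0.18, adjusted p = 0.0492) and more negative for the chloride channel gene Clic4 (-1.22 ± 0.24, adjusted p = 0.0492), the kinase scaffold Spag9 (-1.17 ± 0.21, adjusted p = 0.0403) and the transcription factor Nfia (-0.75 ± 0.14, adjusted p = 0.0403). No other probe set of these 4 genes passed, each call ended under at least 1 alternative, and quantile normalization left 0 calls.

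The age change averaged over the strains was added after the data were seen, because it does not depend on which strain label a 24-month group carries. In aorta (n = 12 at each age) 549 probe sets rose and 258 fell, for 406 and 195 genes. Nnat (2.26 ± 0.21, adjusted p = 2.82e-08), Cpeb1 (1.74 ± 0.16, adjusted p = 2.82e-08) and RT1-CE5 (1.69 ± 0.18, adjusted p = 2.62e-07) rose, and Tfpi rose from 656 ± 173 to 3891 ± 2300 (2.46, adjusted p = 6.01e-07). Inhbb (2.69, adjusted p = 3.82e-05), the bone sialoprotein Ibsp (2.13) and the cartilage matrix protein Comp (1.73) were higher, as were Sphkap (1.83), the vesicle priming gene Cadps (2.05) and Lrrc39 (2.0). Agt (-2.34) and Slc25a1 (-1.48) fell. So did the fatty acid elongase Elovl6 (-1.63), the acyl-CoA synthetases Acsf2 (-1.49) and Acsl5 (-1.30), Pim1 (-1.33) and the GTPase regulator Rap1gap (-1.72). Scgb1c1 (-2.68), the ciliary rootlet gene Crocc (-2.23) and the clock activator Bmal1 (-1.29) were lower. Over the alternatives Inhbb shrank to 1.27 and Lrrc39 to 1.17. In 12 of the 20 genes every 24-month array lay beyond the 6-month mean.

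In aorta at 24 months over both strains, of 14 interferon-stimulated genes 7 rose and 0 fell, 10 when adjusted over the list alone, led by Irf7 (0.95 ± 0.13, adjusted p = 1.8e-05), Gbp2 (0.98 ± 0.14, adjusted p = 4.51e-05) and Isg15 (0.89 ± 0.15, adjusted p = 0.000356). Camera placed the interferon-stimulated list higher (adjusted p = 2.99e-10, and 0.0292 with an estimated correlation). Of 15 macrophage genes 4 rose, 12 when adjusted over the list alone, among them the Fc receptor chain Fcer1g (0.61, adjusted p = 0.000854) and the scavenger receptor Cd163 (0.84, adjusted p = 0.0067). The macrophage list stood higher in camera (adjusted p = 1.33e-07, but 0.353 with an estimated correlation). Of 12 inflammatory genes 4 rose, including Icam1 (1.08, adjusted p = 0.000986) and the adhesion gene Vcam1 (1.33, adjusted p = 0.00724), with 5 adjusted over the list alone. The inflammatory list stood higher in camera (adjusted p = 0.00933, but 0.296 with an estimated correlation).

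In the same comparison, of 9 calcification genes 5 rose, 5 when adjusted over the list alone, among them osteopontin Spp1 (1.55 ± 0.31, adjusted p = 0.00265) and Enpp1, whose pyrophosphate restrains mineral deposition (0.51 ± 0.11, adjusted p = 0.00629). The calcification list stood higher in camera (adjusted p = 0.000234, but 0.226 with an estimated correlation). Of 13 cholesterol synthesis genes 4 fell, 5 when adjusted over the list alone, including Idi1 (-0.78, adjusted p = 0.000615), lanosterol synthase Lss (-0.69) and Fdps (-0.60). The cholesterol list stood lower in camera (adjusted p = 4.83e-09, and 0.00432 with an estimated correlation). Of 40 ribosomal protein genes 11 rose, 22 when adjusted over the list alone, at a median of 0.17. Camera placed the ribosomal list higher (adjusted p = 2.55e-13, but 0.296 with an estimated correlation). None of 74 oxidative phosphorylation genes and none of 9 heat shock genes passed, with camera at adjusted p = 9.57e-06 and 0.0325, and 0.792 and 0.675 with an estimated correlation.

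Single members of other aorta lists passed. The superoxide source Nox4 rose by 1.21 ± 0.35 (adjusted p = 0.0367) and Rac2, a GTPase of the leukocyte oxidase, by 0.59, 2 of 6 NADPH oxidase genes. The angiotensin-converting enzyme gene Ace rose by 0.70 ± 0.18 while Agt fell, 1 each of 8 renin-angiotensin genes. Of 20 matrix genes Postn (0.47) and fibronectin Fn1 (0.73) rose. Of 14 endothelial genes von Willebrand factor Vwf rose by 0.71, and of 10 senescence genes Ccnd1 rose by 1.21 ± 0.19. Fgf1 rose by 1.01 ± 0.12, 1 of 13 growth factor genes. Of 15 unfolded protein response genes the chaperone Calr fell by 0.32. The potassium channel Kcnk3, of the brown adipocyte list, fell by 0.84 ± 0.2 and Fasn, of the white adipocyte list, by 0.74 ± 0.2. None of 17 contractile, 13 ion channel, 10 metalloproteinase, 14 TGF-beta, 6 complement, 7 cell cycle or 16 immediate early genes passed. Leaving out FBN aorta 24-month array 1 raised the count of 807 to 1280, and the calls of Acsl5, Elovl6, Rac2, Nox4, Per2, Uchl1 and Postn ended under at least 1 alternative, and those of Fasn and Crocc when a single array was left out.

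**Figure D2:**
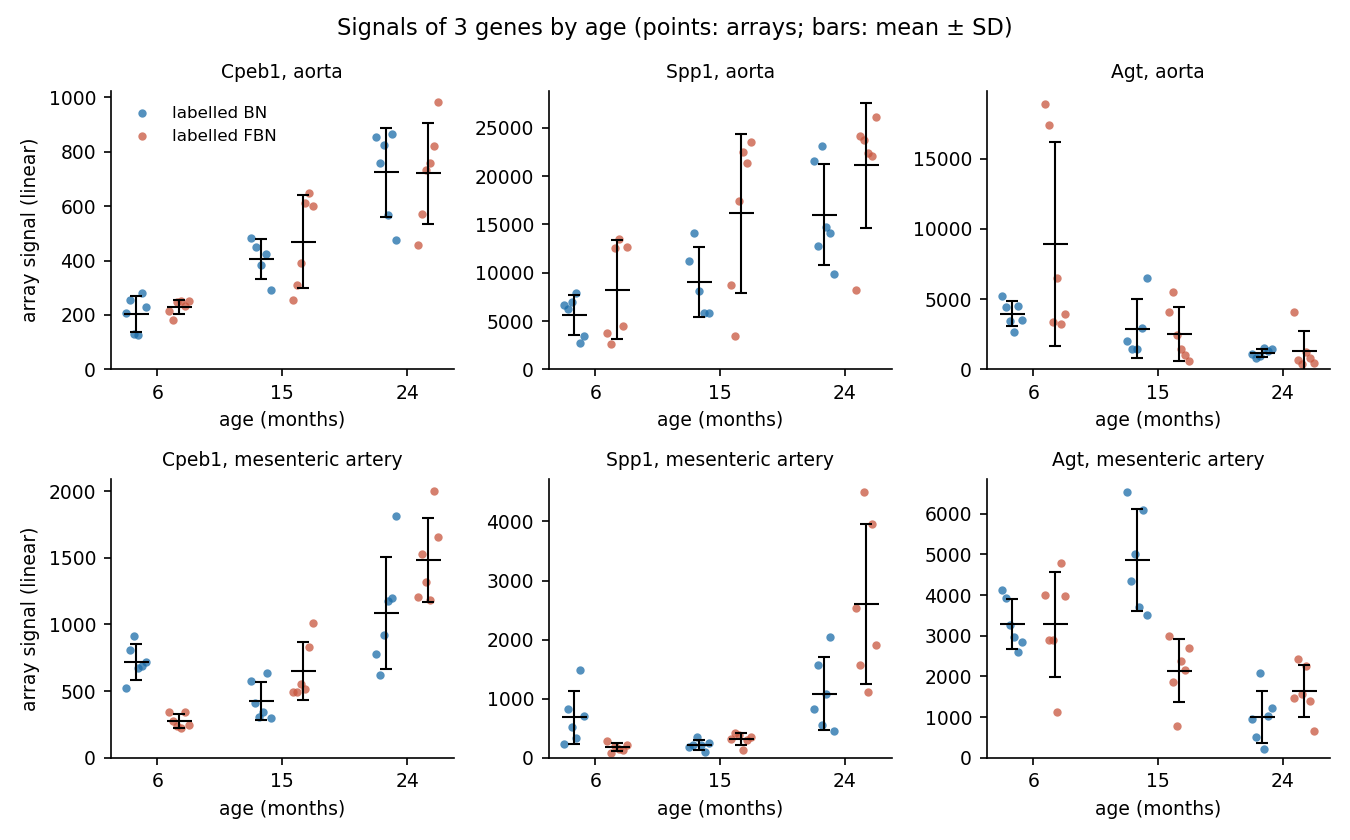
Signals (linear, deposited scale) of Cpeb1, Spp1 and Agt in each array by age, strain label and vessel, with bars for mean ± SD. Over both strains from 6 to 24 months Cpeb1 rose from 217 to 722 in aorta and from 499 to 1285 in mesenteric artery, while Agt fell from 6436 to 1232 and from 3282 to 1321.

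In mesenteric artery, 24 and 6 months were compared over both strains (n = 12 each). Spp1 rose from 432 ± 406 to 1843 ± 1280 (2.26 ± 0.29, adjusted p = 5.05e-06). Cpeb1 rose from 499 ± 250 to 1285 ± 411 (1.47 ± 0.16, adjusted p = 1.97e-07) and Ltbp2, which binds elastic microfibrils, rose 3.67-fold (1.88 ± 0.26, adjusted p = 2.41e-05). Nupr1, a stress-response chromatin gene, rose by 1.13 ± 0.1 (adjusted p = 9.42e-09). Agt fell from 3282 ± 959 to 1321 ± 696 (-1.49 ± 0.27, adjusted p = 0.000806) and the organic cation transporter Slc22a3 fell by 1.41 ± 0.18 (adjusted p = 5.05e-06).

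Further genes higher in 24-month mesenteric artery were the endothelial proteoglycan Esm1 (1.85, adjusted p = 4.39e-05), the calcium sensor Vsnl1 (1.29, adjusted p = 5.6e-07), the matricellular Ccn5 (1.18, adjusted p = 2.41e-05), the secreted Fibin (1.18, adjusted p = 0.000368) and Srpx2 (1.37, adjusted p = 0.00111), and the clock output gene Dbp (1.82, adjusted p = 0.0188). Lower genes included the fat cell galectin Lgals12 (-1.27, adjusted p = 0.000368), the fatty acid desaturase Scd (-1.66, adjusted p = 0.0164), the imprinted Mest of adipose expansion (-1.38) and the amino acid transporter Slc36a2 (-1.23). The cyclic AMP binding Popdc3 (-2.28), the homeobox gene Zfhx2 (-1.65), the ankyrin repeat gene Ankef1 (-1.28) and the ceramide gene Tlcd3b (-1.28) were lower too, Popdc3 shrinking to -0.82 and Zfhx2 to -0.71 over the alternatives. In 15 of the 20 genes every 24-month array lay beyond the 6-month mean.

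Of 9 calcification genes in mesenteric artery 3 rose, Spp1, Comp (0.96 ± 0.14, adjusted p = 4.39e-05) and Mgp (0.26 ± 0.054, adjusted p = 0.00221, but 0.13 with quantile normalization), with 4 adjusted over the list alone. Mgp is an inhibitor of calcification. Camera placed the calcification list higher (adjusted p = 8.13e-06, and 0.00148 with an estimated correlation). Of 14 TGF-beta genes 4 rose, 4 when adjusted over the list alone, among them the ligand Tgfb1 (0.48 ± 0.099, adjusted p = 0.0027) and its binding protein Ltbp1 (0.44, adjusted p = 0.0124). The TGF-beta list stood higher in camera (adjusted p = 0.0125, but 0.222 with an estimated correlation). Of 20 matrix genes 5 rose and 0 fell, including the elastin cross-linking Loxl1 (0.54), Fn1 (0.64) and Fbln5 (0.49). Camera did not call the matrix list (adjusted p = 0.171). Of 13 basement membrane genes 3 fell, among them nidogen Nid2 (-0.67).

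Of 15 white adipocyte genes in mesenteric artery 5 fell, 7 when adjusted over the list alone, including Fasn (-0.97) and the lipid droplet coat Plin1 (-1.0), with Acaca also lower. The white adipocyte list stood lower in camera (adjusted p = 5.31e-06, but 0.414 with an estimated correlation). Of 40 ribosomal protein genes 29 rose, 37 when adjusted over the list alone, Rpl12 among them (0.34). Ribosomal proteins stood higher in camera (adjusted p = 3.5e-29, but 0.0652 with an estimated correlation). Of 36 proteasome genes 3 rose, 9 higher and 1 lower when adjusted over the list alone, Psmc1 among them (0.25). The proteasome list stood higher in camera (adjusted p = 1.44e-05, but 0.27 with an estimated correlation). Of 9 nerve genes 1 rose and 3 fell, the neuronal ubiquitin hydrolase Uchl1 (0.97) against myelin basic protein Mbp (-0.70). Of 14 endothelial genes the receptor Flt1 fell by 0.55, and camera's adjusted p = 0.0385 became adjusted p = 0.701 with an estimated correlation. Of 13 cholesterol genes Dhcr7 fell by 0.80 ± 0.13, with camera at adjusted p = 0.0385, but 0.414 with an estimated correlation. None of 9 heat shock genes passed, with camera at adjusted p = 0.0499, but 0.671 with an estimated correlation.

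Nox4 rose by 0.79 ± 0.23 (adjusted p = 0.0292), 1 of 6 NADPH oxidase genes in mesenteric artery. The p53 target Ccng1 rose by 0.45 ± 0.062 and Igfbp5 fell by 0.45, from a senescence list with 2 higher and 2 lower of 10. Of 17 antioxidant genes 3 rose, glutathione reductase Gsr among them (0.51), and catalase Cat fell by 0.27. Of 12 inflammatory genes 3 rose, Ccl5 by 0.63. Of 10 metalloproteinase genes Adamts4 fell by 0.79 and Timp2 rose by 0.25. Of 13 ion channel genes 2 rose, Trpm4 by 0.34 and Kcnq5 by 0.39. Of 13 growth factor genes the receptor Pdgfrb rose by 0.34 and Vegfa fell by 0.49. None of 17 contractile, 14 interferon-stimulated, 15 macrophage, 8 class II, 8 mesothelium or 15 unfolded protein response genes passed.

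In mesenteric artery 499 probe sets rose and 552 fell, for 366 and 393 genes. Of 57 genes named in mesenteric artery 29 lost the call under at least 1 alternative, Dbp, Scd, Tlcd3b, Bmal1, Nr1d2, Per3, Tef, Bhlhe41, Acaca, Plin1, Nox4, Loxl1, Ltbp1, Uchl1, Mbp and Flt1 among them. The poly-A spike-in signal was lower by 1.86 log2 at 24 than at 6 months in arrays labelled FBN (exact permutation test, two-sided, adjusted p = 0.0479), and the difference was 0.65 in those labelled BN (adjusted p = 0.329). With this signal as a covariate, chosen after the data were seen, 1669 probe sets passed in place of 1051.

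Circadian clock genes changed with age in both vessels. Of 16 genes 5 rose and 3 fell in aorta, 8 and 3 when adjusted over the list alone, and 8 rose and 2 fell in mesenteric artery, 10 and 4 when adjusted over the list alone. Camera gave adjusted p = 0.145 in aorta, and in mesenteric artery adjusted p = 0.0247, but 0.23 with an estimated correlation. The activators Npas2 (-1.08 ± 0.27 in aorta, -1.21 ± 0.24 in mesenteric artery) and Bmal1 (-1.29 and -0.96) fell in both vessels. The repressors Bhlhe41 (1.44 ± 0.2 and 0.93), Nr1d2 (1.04 and 0.98), Per2 (0.65 and 0.99) and Per3 (1.66 and 1.08) and the output gene Tef (0.58 and 0.68) rose in both. Nfil3 fell in aorta (-1.20 ± 0.17, adjusted p = 3.82e-05) and did not pass in mesenteric artery (-0.84, adjusted p = 0.07). Dbp passed in mesenteric artery (1.82, adjusted p = 0.0188) and not in aorta (1.31, adjusted p = 0.0581). Tested directly, the age change of neither gene differed between vessels (Nfil3 adjusted p = 0.71, Dbp adjusted p = 0.79). The time of day of collection is not given in the sources used here.

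**Figure D3:**
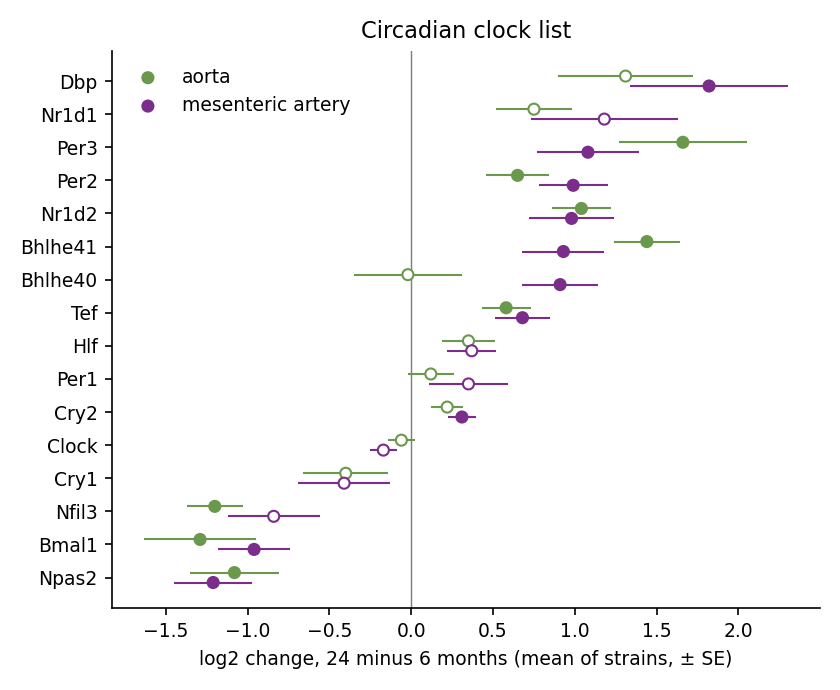
Log2 change from 6 to 24 months, averaged over strains, ± standard error, of circadian clock genes in aorta and mesenteric artery, where filled points passed an adjusted p of 0.05 and open points did not. Npas2 fell in both vessels (-1.08 and -1.21) and Per3 rose in both (1.66 and 1.08).

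The 2 vessels shared 151 called probe sets, 136 of them in the same direction (92 higher, 44 lower) where 24.9 were expected for independent lists. Besides Spp1, Cpeb1, Comp and Agt, Esm1 (1.11 in aorta, 1.85 in mesenteric artery), Srpx2 (1.53 and 1.37) and Uchl1 (1.5 and 0.97) rose in both, and 1 of 2 probe sets of the fibrillar collagen gene Col1a1 fell in both (-1.17, adjusted p = 0.0249, and -0.93, adjusted p = 0.00193). The difference of the age changes between vessels, tested directly, passed for 138 probe sets higher and 49 lower. Inhbb (3.01, adjusted p = 4.02e-05), Tfpi (2.66, adjusted p = 2.27e-09) and Nnat (2.63, adjusted p = 1.41e-05) had the more positive change in aorta, while in mesenteric artery their changes of -0.32, -0.20 and -0.37 did not pass (adjusted p = 0.507, 0.123 and 0.53). Inhbb shrank to 1.52 over the alternatives. Slc25a1 (-1.27, adjusted p = 0.00416), Acsf2 (-1.36, adjusted p = 0.0475) and the p53-induced Tp53inp1 (-1.44, adjusted p = 0.049) changed more negatively in aorta, and Acsf2 and Tp53inp1 lost the call under at least 1 alternative.

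In mesenteric arrays labelled BN, 24 and 6 months were compared as deposited (n = 6 each), with 234 probe sets higher and 239 lower. Agt fell from 3286 ± 618 to 1005 ± 645 (-2.0 ± 0.38, adjusted p = 0.00125), and so did the adrenergic receptor Adrb3 of fat cells (-1.40 ± 0.35, adjusted p = 0.0187), Slc22a3 (-1.75 ± 0.25, adjusted p = 1.98e-05), Lgals12 (-1.67) and Slc36a2 (-1.87). Albumin Alb (-2.47 ± 0.58, adjusted p = 0.0103), the keratin Krt79 (-2.98), Hrh3 (-2.12), the laminin Lamb3 (-1.85) and Popdc3 (-2.48) were lower. The 10 higher genes, all with a strain difference at 6 and 15 months too, were the guanine exchange factor Trio (3.68), Echdc2 (3.51), Msrb3 (2.90), Dmp1 (2.02), Prps2 (1.89), Grifin (1.80) and the collagen-binding integrin Itga1 (1.69), Ibsp (2.84), the class II gene RT1-Ba (1.84) and the G-protein subunit Gnas (1.59). Krt79 and Ibsp signals were near background (101.9 to 10.2, and 9.3 to 73.4), and over the alternatives their values shrank to -0.91 and 0.72, that of Popdc3 to -0.81, Hrh3 to -1.13, Lamb3 to -1.18 and Dmp1 to 1.25. RT1-Ba has another probe set that went the other way (-1.06), and other probe sets of Trio and Msrb3 did not change.

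Of 14 endothelial genes in these arrays Flt1 fell (-0.76 ± 0.2, adjusted p = 0.0314), with 1 higher and 8 lower when adjusted over the list alone. Of 15 white adipocyte genes Fasn fell (-0.88, adjusted p = 0.0365), 6 when adjusted over the list alone. Camera called both lists lower (adjusted p = 2.74e-05 and 1.47e-05), but 0.708 and 0.714 with an estimated correlation. Hyou1, a chaperone of the unfolded protein response list, fell by 0.85 ± 0.14 (adjusted p = 0.000246). Popdc3, Krt79, Adrb3, Fasn and Flt1 lost their calls under at least 1 alternative, and Ibsp when a single array was left out.

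From 6 to 15 months, with labels the marker score follows, 287 probe sets rose and 296 fell in BN mesenteric artery. Scd rose by 2.79 ± 0.61 (adjusted p = 0.00816), with the antileukoproteinase-like Wfdc21 (1.31) and proline dehydrogenase Prodh (1.23). Spp1 fell by 1.47 ± 0.4 (adjusted p = 0.0363), as did the mannose enzyme gene Pmm2 (-1.57) and the steroidogenic Cyp11a1 (-1.49). Of these 6 genes only Scd passed under every alternative, Prodh shrank to 0.79, Pmm2 to -0.86 and Cyp11a1 to -0.87, and Cpeb1 fell by 0.80 (adjusted p = 0.0369). Poly-A and hybridization spike-in signals were 1.2 and 0.55 log2 higher at 15 months (exact permutation tests, two-sided, adjusted p = 0.00972 each), while end to start ratios of Gapdh (0.41, adjusted p = 0.0583) and Actb (0.58, adjusted p = 0.0972) did not pass. With poly-A signal as a covariate Prodh, Spp1, Pmm2 and Cyp11a1 lost their calls. Ribosomal proteins had a median change of 0.13, which became -0.06 with quantile normalization. From 15 months to the 24-month arrays labelled BN, 1369 rose and 1364 fell, among them Trio (3.98), Msrb3 (3.25) and Echdc2 (3.13) higher and Popdc3 (-2.95, shrinking to -1.01 over the alternatives), the globin Hba-a3 (-2.55) and Agt (-2.55 ± 0.38, adjusted p = 1.86e-05) lower.

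In mesenteric arrays labelled FBN, 24 and 6 months were also compared as deposited (n = 6 each), with 1523 probe sets higher and 1232 lower. Spp1 rose 13.9-fold, from 177 ± 67.1 to 2599 ± 1350 (3.80 ± 0.4, adjusted p = 2.57e-08), and Ltbp2 rose 11.8-fold (3.57 ± 0.37, adjusted p = 1.32e-08). Cpeb1 (2.41 ± 0.22, adjusted p = 8.34e-10), Nupr1 (2.44 ± 0.15, adjusted p = 4.67e-14), Esm1 (2.72 ± 0.38, adjusted p = 5.4e-06), Ccn5 (2.11), Srpx2 (2.04) and the BMP antagonist Grem1 (2.14) rose, as did Dbp (2.84) and the lipase inhibitor Angptl8 (2.40). Scd fell from 4748 to 232 (-4.40). The lipid droplet lipase gene Pnpla3 (-2.05), Npas2 (-1.93), the aryl hydrocarbon target Tiparp (-1.81) and Popdc3 (-2.08) fell. The strain-separating genes Trio (-3.81), Echdc2 (-3.46), Msrb3 (-2.93), Dmp1 (-2.03) and Itga1 (-1.86) were lower. Over the alternatives Angptl8 shrank to 0.13, Grem1 to 1.34, Pnpla3 to -1.11, Tiparp to -1.1, Popdc3 to -0.82 and Dmp1 to -1.35. In all 20 genes every 24-month array lay beyond the 6-month mean.

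Of 9 calcification genes in these arrays 4 rose, among them Comp (1.57 ± 0.2, adjusted p = 7.64e-07), and camera gave adjusted p = 0.000588, and 0.017 with an estimated correlation. Of 14 TGF-beta genes 4 rose, Tgfb1 by 0.74 ± 0.14 and Ltbp1 by 0.83 ± 0.15, with camera at adjusted p = 0.0359, but 0.295 with an estimated correlation. Of 20 matrix genes 5 rose and 1 fell, Fn1 rising by 1.19 ± 0.16 (adjusted p = 3.83e-06). Ribosomal proteins (29 of 40 higher) and proteasome genes (14 of 36 higher) had camera adjusted p = 2.22e-19 and 1.41e-06, but 0.254 for each with an estimated correlation. Angptl8, Popdc3, Dbp, Pnpla3 and Ltbp1 lost their calls under at least 1 alternative, exchanged strain labels not among them. From 6 to 15 months Cpeb1 (1.19 ± 0.22, adjusted p = 0.0441) and the endothelial transcription factor Erg (0.84 ± 0.15, adjusted p = 0.0441) passed, neither under every alternative, and 1876 probe sets had an unadjusted p under 0.05 in limma. In 7 of 100 splits as many probe sets passed or more, up to 2271. From 15 months to the 24-month arrays labelled FBN 427 rose and 358 fell, Ltbp2 (3.00), Spp1 (2.95) and the interleukin receptor Il1rl2 (2.05, shrinking to 1.2 over the alternatives) among those higher and Trio (-3.80), Echdc2 (-3.31) and Msrb3 (-3.02) among those lower.

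The labelled BN and FBN age changes in mesenteric artery shared 242 called probe sets, of which 40 had the same direction where 38.9 were expected, and correlated at r = -0.16 across probe sets. With the strain labels of the 24-month arrays exchanged, an alternative added after the data were seen, 70 probe sets passed in place of 785 for FBN at 24 against 15 months, 16 of them under both. For BN at 24 against 15 it was 1133 in place of 2733, and for FBN at 24 against 6 months 1146 in place of 2755. The strain by age difference called 853 probe sets higher and 744 lower. It was led by Krt79 (4.26 ± 1.1, adjusted p = 0.0118), Alb (3.53 ± 0.82), Ltbp2 (3.38 ± 0.52), Trio (-7.49 ± 0.21), Echdc2 (-6.97 ± 0.36) and Msrb3 (-5.83 ± 0.34). Krt79 and Alb shrank to 1.24 and 1.66 and lost the call under at least 1 alternative, with exchanged labels 632 passed, and the direction follows strain labels that the marker genes contradict.

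FBN and BN aortas were compared over the 3 ages (n = 18 and 17). Dmp1, a matrix phosphoprotein of bone and dentin, was higher in FBN, at 3578 ± 1970 against 109 ± 33.7 (4.78 ± 0.31, adjusted p = 1.93e-13). Trio (3.80 ± 0.14, adjusted p = 1.6e-19), the angiotensin receptor Agtr1b (2.73 ± 0.35, adjusted p = 6.8e-07) and Itga1 (2.62 ± 0.15) were higher as well. Lower genes included Elovl6 at 5062 ± 7970 against 19371 ± 8650 (-2.88 ± 0.38, adjusted p = 1.01e-06), malic enzyme Me1 at 7454 against 28686 (-2.56 ± 0.34) and the acetyl-CoA carboxylases Acaca (-2.55 ± 0.49, adjusted p = 0.000131) and Acacb (-2.45 ± 0.49, adjusted p = 0.000172). In 9 of the 20 named genes every FBN array lay beyond the BN mean.

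Also higher in FBN aorta were the methionine sulfoxide reductase Msrb3 (3.39), Echdc2 of mitochondrial lipid metabolism (3.19), the matrix fibulin Fbln1 (2.27), the nucleotide synthesis gene Prps2 (2.12), the DNA-binding Fubp3 (2.15) and the ring finger gene Rnf207 (2.37 ± 0.5, adjusted p = 0.000338). Lower were myoglobin Mb (-2.64 ± 0.4, adjusted p = 7.29e-06), Scgb1c1 (-2.57), the retinol dehydrogenase Dhrs9 (-2.54, adjusted p = 0.000286), the Ras effector Rassf4 (-2.50), Krt79 (-2.49) and Rap1gap (-2.46 ± 0.28, adjusted p = 7.06e-08). Another probe set of Fubp3 went the other way (-0.44, adjusted p = 4.89e-05), and another of Trio differed by only 0.13 at 6 and 15 months.

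In FBN aorta all 15 white adipocyte genes and 9 of 10 brown adipocyte genes were lower, Scd (-1.73) and the muscle-type fatty acid binding Fabp3 (-1.99 ± 0.32, adjusted p = 1.49e-05) among them, with 15 and 9 adjusted over the list alone. Of 74 oxidative phosphorylation genes 2 were higher and 69 lower, 3 and 69 when adjusted over the list alone, at a median of -0.68. By camera these 3 lists had adjusted p = 1.88e-05, 0.00168 and 3.04e-12, but 0.854 for each with an estimated correlation. Of 17 contractile genes 11 were higher, 13 when adjusted over the list alone, including the actin Acta2 (0.86 ± 0.23, adjusted p = 0.00229), phospholamban Pln (1.38) and smoothelin Smtn (1.08). Of 40 ribosomal protein genes 37 were higher and of 20 matrix genes 10 were higher and 1 lower, Sparc by 0.76 ± 0.15. In camera these had adjusted p = 0.00616, 6.14e-12 and 0.0344, but 0.92, 0.854 and 0.92 with an estimated correlation. Of 17 antioxidant genes 12 passed, 11 lower, Cat by -1.0 ± 0.2. Of 8 renin-angiotensin genes 6 passed, 5 higher, and all 13 growth factor genes did, 9 higher.

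In FBN aorta 5187 probe sets were higher and 4503 lower, 57.96% of those tested. Poly-A spike-in signals were higher in FBN aorta by 0.72 log2 at 6 and 1.09 at 24 months (exact permutation tests, two-sided, adjusted p = 0.0142 and 0.00972) and not at 15 (-0.25, adjusted p = 0.135), where hybridization signals were lower by 0.63 (adjusted p = 0.00972). With poly-A signal as a covariate 3299 were called, with tissue mass 3513. With the brown adipocyte score as a covariate, chosen after the data were seen, 2251 were called, 1595 of them also without it and 1565 in the same direction. With that covariate 0 contractile, 0 growth factor and 0 matrix genes were higher, and 1, 1 and 6 lower. Of white adipocyte genes 2, and of oxidative phosphorylation genes 0, were lower. Of 40 ribosomal genes 20, all called without it, were higher and 0 lower. Rnf207 (0.54), Scgb1c1 (-0.99), Acaca (-0.67), Dhrs9 (-0.66), Acacb (-0.54), Scd (-0.57), Pln (0.17), Smtn (0.06), Sparc (0.18) and Cat (-0.15) lost their calls, and Acta2 turned from 0.86 to -0.03, while Trio (3.32), Dmp1 (3.70), Echdc2 (3.70), Itga1 (2.20) and Agtr1b (1.88) passed. Elovl6 (-1.24), Me1 (-1.21), Mb (-1.25), Fabp3 (-0.70), Rassf4 (-1.32), Krt79 (-1.06) and Rap1gap (-1.45) passed with smaller values.

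Tissue mass and adipocyte score were related within FBN aorta. Over 18 arrays mass and brown adipocyte score correlated at r = 0.80 (permutation test, two-sided, adjusted p = 0.000587; rho = 0.78, adjusted p = 0.00062), and at r = 0.86 without the 2 arrays of most extreme mass. In BN aorta (n = 17) r was 0.34 (adjusted p = 0.205; rho = 0.38, adjusted p = 0.154). The contractile score fell as the brown adipocyte score rose, with r = -0.89 in FBN (adjusted p = 8e-05; rho = -0.86, adjusted p = 0.00024) and -0.73 in BN aorta (adjusted p = 0.00132; rho = -0.79, adjusted p = 0.00062). Without the 2 most extreme arrays these were -0.85 and -0.72. In all, 8 relations were computed, and arrays of the 3 ages were pooled.

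**Figure D4:**
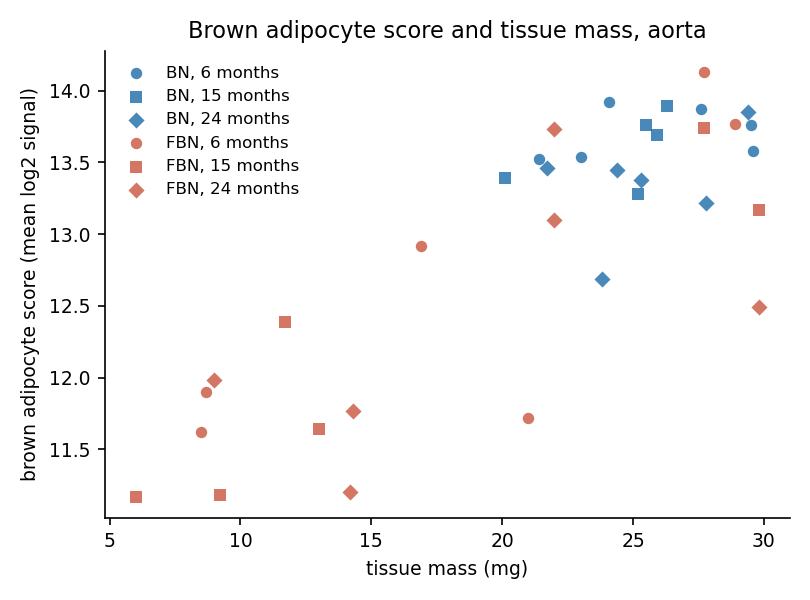
Tissue mass (mg) against brown adipocyte score (mean log2 signal of 10 marker genes) in each aorta array, by strain. In FBN aorta the score rises with mass (r = 0.80, 18 arrays), while in BN aorta r is 0.34 (17 arrays).

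FBN and BN mesenteric arteries were compared at 6 and 15 months alone (n = 12 each), a comparison added after the strain markers had been seen. Trio was higher in FBN, at 3426 ± 470 against 243 ± 56.7 (3.85 ± 0.1, adjusted p = 3.01e-25), as were Echdc2 (3.29), Msrb3 (2.92), Dmp1 (2.21 ± 0.21, adjusted p = 1.07e-09) and Itga1 (1.69 ± 0.14, adjusted p = 6.2e-11). The eosinophil chemokine Ccl11 (-1.70 ± 0.36, adjusted p = 0.00155), complement C3 (-1.52 ± 0.29, adjusted p = 0.000547), the matrix tenascin Tnc (-1.29) and Grem1 (-1.28) were lower. Prps2 (1.74), Grifin (1.79), Fubp3 (1.49), Ibsp (1.93) and the nuclear receptor Nr4a3 (1.93) were higher. RT1-Ba (-1.38), Lamb3 (-1.37), Hrh3 (-1.49), the carbonyl reductase Cbr3 (-1.23), Hba-a3 (-1.19) and the phosphatase Ptpn4 (-1.18) were lower. Over the alternatives Ibsp shrank to 0.48, Dmp1 to 1.35, Ccl11 to -1.01, C3 to -0.98, Grem1 and Cbr3 to -0.74, RT1-Ba to -0.85, Hrh3 to -0.79 and Ptpn4 to -0.58. In 16 of the 20 genes every FBN array lay beyond the BN mean.

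Another probe set of RT1-Ba (1.25) and 1 of Fubp3 (-0.36) went the other way. Nr4a3 had 1 at -0.02 and Trio 1 at -0.09. The Trio value above thus rests on 1 probe set. Of 8 class II genes RT1-Ba alone fell, and of 16 immediate early genes Dusp1 (0.35 ± 0.1, adjusted p = 0.0299) and Zfp36 (0.60 ± 0.18, adjusted p = 0.0374) were higher. Camera called both lists at adjusted p = 0.0067, but 0.927 with an estimated correlation. Of 14 endothelial genes Vwf was lower (-0.85) and 1 was higher. Of 7 cell cycle genes Mcm6 was lower (-0.43), and of 8 mesothelium genes 1 was lower, 5 when adjusted over the list alone. The endothelial, cell cycle and mesothelium lists had camera adjusted p = 0.0434, 0.0214 and 0.0201, but 0.927 for each with an estimated correlation. Of 6 complement genes C3 was lower. The potassium channel Kcna2 (0.84) and Agtr1b (0.69) were higher.

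At 6 and 15 months 642 probe sets were higher and 656 lower, for 436 and 450 genes, and Zfp36 and Kcna2 lost their calls under an alternative, and Hba-a3 when a single array was left out. Poly-A spike-in signals were 2.01 log2 higher in FBN than in BN mesenteric artery at 6 months (exact permutation test, two-sided, adjusted p = 0.00972) and 0.51 at 15 (adjusted p = 0.376), and with this signal as a covariate Ccl11, Hrh3, Grem1, Ptpn4, Agtr1b, Mcm6, Vwf and Dusp1 lost their calls. The aorta and this comparison shared 820 called probe sets, 678 of them in the same direction where 375.9 were expected. Over the 3 ages as labelled, 174 probe sets were higher and 172 lower. Trio (1.30), Echdc2 (1.06), Dmp1 (0.92), Msrb3 (0.90), the actin-binding Afap1 (0.62), Ssr3 (0.59), RT1-CE12 (0.57), Larp1 (0.57), Basp1 (0.56) and Prps2 (0.56) were higher in arrays labelled FBN. Mga (-0.93), C3 (-0.88), the growth factor binding Igfbp5 (-0.82), Raph1 (-0.70), Fcrl2 (-0.70), the kinase Rps6ka5 (-0.65), Zfp451 (-0.61), Nrk (-0.61), Bhlhe22 (-0.60) and the focal adhesion gene Tns1 (-0.57) were lower. RT1-CE12, C3, Fcrl2, Afap1, Bhlhe22, Basp1, Zfp451 and Nrk lost their calls under at least 1 alternative, as did Ssr3 without a single array, and Afap1 shrank to 0.34, Larp1 to 0.35, Dmp1 to 0.55 and Fcrl2 to -0.43. With exchanged labels 1912 probe sets passed, and all values here include the 24-month arrays whose labels the marker genes contradict.

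The vessels were compared over both strains and the 3 ages (n = 35 aorta and 36 mesenteric arrays). Cox8b, a muscle and brown fat subunit of cytochrome oxidase, had a signal of 43859 ± 16200 in aorta and 17.9 ± 15 in mesenteric artery (adjusted p = 1.84e-51). Its log2 difference was 11.53, and 8.69 with an offset, and that of Ucp1 11.07, and 9.18 with an offset, since the mesenteric signals were near background. Scd was at 45474 in aorta and 1804 in mesenteric artery (5.30). Sox2, a transcription factor of glia and progenitor cells, was lower in aorta (-5.24 ± 0.26, adjusted p = 5.41e-28), as was apolipoprotein Apod, at 161 against 6746 (-5.71). Adgrb3, an adhesion receptor of nerve tissue, was near background in aorta, at 7.2 against 396 (-6.97, and -2.32 with an offset). Signals near background in 1 vessel made other values depend on the offset too, with which Sox2 was at -2.70, Cmtm5 at -3.43, Rup2 at 4.40, Sphkap at 3.43 and Acacb at 2.95. The urinary protein gene Rup2 (6.94), Sphkap (5.90), Tmem79 (5.68), the liver-type glycogen synthase Gys2 (5.41), Cyp2e1 (5.32), the myosin binding Mybpc2 (5.22) and Acacb (5.14) were higher in aorta. The nociceptin precursor Pnoc (-6.13), the glial channel Ttyh1 (-5.94), Mlip (-5.65), Zfp536 (-5.33), Tmem51 (-5.24), Igsf11 (-5.20) and the myelin-associated Cmtm5 (-5.17) were lower. In all 20 genes every aorta array lay beyond the mesenteric mean.

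Brown adipocyte genes (10 of 10) and white adipocyte genes (15 of 15) were higher in aorta, and 72 of 74 oxidative phosphorylation genes were, at a median of 1.45. Camera gave adjusted p = 5.31e-08, 5.31e-08 and 2.76e-26, but 0.373, 0.42 and 0.42 with an estimated correlation. Nerve genes (8 of 9) were lower in aorta, including the Schwann cell factor Sox10 (-3.79) and Mbp (-3.49), as were 12 of 13 basement membrane genes, Lama5 among them (-1.98). Of 17 contractile genes 1 was higher and 15 lower, with desmin Des at -2.54 ± 0.16 and Pln at -2.42 ± 0.16. Camera gave adjusted p = 0.0256, 0.0216 and 0.035 for these, but 0.396, 0.42 and 0.851 with an estimated correlation. Of 36 proteasome genes 28 were higher, and of 17 antioxidant genes 10 were, Sod2 by 2.35. Of 9 heat shock genes 6 were higher, Hspe1 by 1.53, and of 13 cholesterol genes 7 were, Fdps by 1.32. Camera gave adjusted p = 0.000101, 0.0344, 0.035 and 0.035 for these 4 lists, but 0.42, 0.582, 0.621 and 0.42 with an estimated correlation. Of 13 Hox genes, which mark body position, 3 were higher and 10 lower, Hoxa5 by 1.38 ± 0.078 and Hoxc8 by -2.0 ± 0.11.

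Between vessels 5798 probe sets were higher in aorta and 8195 lower. The median over all probe sets was -0.122 as deposited and -0.015 with arrays centred on their medians, a shift of the scale that the changes named above exceed. The difference of the strain effect between vessels, tested directly, called 3811 probe sets higher and 3184 lower in aorta. Dmp1 (3.85 ± 0.35), Trio (2.50) and Msrb3 (2.49) had the most positive values, and Dhrs9 (-3.02), Elovl6 (-2.90 ± 0.39) and Krt79 (-2.89, shrinking to -1.9 over the alternatives) the most negative. These include the 24-month mesenteric arrays with contradicted labels. At 6 and 15 months in mesenteric artery the strain difference was 3.85 for Trio and 2.92 for Msrb3, against 3.80 and 3.39 in aorta, so the value of Trio, and most of that of Msrb3, rests on those labels.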

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

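Chosen only after the result was seen were the tests on strain marker levels, spike-in signals, the comparisons averaged over strains, the strain comparison at 6 and 15 months, and the brown adipocyte score as a covariate.

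Single arrays stood far from the other arrays of their group in 8 of 132 Dixon tests, and chance flags about 1 in 20 groups. FBN aorta 15-month array 1 had log2 ratios of end to start signal of 1.21 for Gapdh (others 0.23 to 0.43) and 1.47 for Actb (others 0.76 to 0.96). BN aorta 24-month array 4 had a median signal of 282.12 (others 296.39 to 304.17). FBN aorta 24-month array 3 had a poly-A spike-in level of 12.13 (others 9.92 to 10.75), and array 1 of that group a contractile score of 13.05 (others 14.17 to 14.7). The hybridization spike-in level was 13.44 in array 4 of the 24-month mesenteric arrays labelled BN (others 12.57 to 12.75) and 13.43 in FBN mesenteric 6-month array 2 (others 12.59 to 12.89). That last array had a nerve score of 11.19 (others 10.46 to 10.71).

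Group differences in effect size came from direct interaction tests. The strain by age difference in aorta passed for 5 probe sets, with Cav2 at 0.96, Clic4 at -1.22, Spag9 at -1.17 and Nfia at -0.75. In mesenteric artery as labelled it passed for 1597, with Krt79 at 4.26, Alb at 3.53, Ltbp2 at 3.38, Trio at -7.49, Echdc2 at -6.97 and Msrb3 at -5.83. The age change differed between vessels for 187, with Inhbb at 3.01, Tfpi at 2.66, Nnat at 2.63, Tp53inp1 at -1.44, Acsf2 at -1.36 and Slc25a1 at -1.27. The strain effect differed between vessels for 6995, with Dmp1 at 3.85, Trio at 2.50, Msrb3 at 2.49, Dhrs9 at -3.02, Elovl6 at -2.90 and Krt79 at -2.89. Trio, most of Msrb3 and part of Dmp1 rest on 24-month labels that the markers contradict.

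The inversion of strain differences in 24-month mesenteric arrays may come from exchanged strain labels. All 12 arrays of both groups lay on the other strain's side of 24 markers, 0 of the 36 other arrays not used to choose the markers did, and the markers' 24-month strain difference was -1.04 times that at 6 and 15 months (SD 0.22), against 0.98 in aorta. With markers of any gap (108) the count was 6 of 12 and 7 other arrays, all mesenteric, also lay on the other side, and with the mesenteric midpoint it was 12 of 12 and 0 at each gap (108, 24 and 10 markers). A biological inversion was tested on 7 other probe sets of the marker genes (median absolute strain difference 0.36). Those of Prps2 (1.41 to -1.61, 1.54 to -1.91), Rtel1, Fubp3 and Pxmp4 inverted, as both explanations allow. Those of Trio (-0.09) and Trak2 (0.19), which differed least, did not, so the question stays open. With labels exchanged mesenteric strain by age called 632 probe sets, 103 also as labelled (66 in the same direction).

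The strain difference in aorta is consistent with a smaller share of surrounding adipose tissue in FBN samples. Within FBN aorta arrays, with age means removed, the change per unit fall of the brown adipocyte score correlated with the strain difference at r = 0.85 across probe sets (-0.85 per unit rise), although the brown fat axis of these arrays had been seen before this test. A strain difference present in both vessels is a second explanation, since 61.1% of the probe sets called in aorta had the same sign at 6 and 15 months in mesenteric artery, barely above the 60% set for it and against 56.7% of all tested. Both explanations stay open and may hold together. With the score as a covariate 2251 probe sets were called, 1565 of them among the 9690 and in the same direction, Trio, Dmp1 and Itga1 included, while the contractile list went from 11 higher to 0 higher and 1 lower.

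Clock genes that changed with age in both vessels may reflect arrays of different ages collected at different times of day. After group means were removed, the mean of 10 genes that peak with Dbp and the mean of 5 that peak with Bmal1 correlated at -0.91 in mesenteric artery (n = 36) and -0.93 in aorta (n = 35), each with adjusted p = 1e-05, the smallest that the permutations can give. This pattern within groups follows from the clock's own wiring as well, so a time of day and an age change of the clock cannot be told apart without collection times. No biological explanation was tested beyond the age groups themselves.

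Chance could be excluded where fewer than 5 of 100 random splits of the arrays, the real one included, called as many probe sets. The limit was met for BN aorta at 24 against 6 months (1 split; 210 real, 30 the highest other), 15 against 6 (1; 111, 2) and 24 against 15 (1; 42, 2). It held for FBN aorta at 24 against 15 months (1; 35, 6), for the strain difference in aorta (1; 9690, 4682) and for the age change over strains in aorta (2; 807, 1946). It held for the mesenteric arrays labelled BN at 24 against 6 (1; 473, 174), 15 against 6 (1; 583, 0) and 24 against 15 months (1; 2733, 1737), and for those labelled FBN at 24 against 6 (1; 2755, 1180) and 24 against 15 months (1; 785, 334). In mesenteric artery it held for the strain difference at 6 and 15 months (1; 1298, 205), for the strain by age difference (1; 1597, 446) and for the age change over strains (1; 1051, 78). Between vessels it held for the main difference (1; 13993, 0), by age (1; 187, 8) and by strain (1; 6995, 3205).

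Chance could not be excluded for FBN aorta at 24 against 6 months (9 splits; 185 real, 8201 the highest other) and 15 against 6 months (18; 1, 8652), or for FBN mesenteric artery at 15 against 6 months (7; 2, 2271). The aorta strain by age difference met the limit (3 splits, 5 real, 3879 highest), but chance stays open, as quantile normalization left 0. Splits with several times the real count point to a structure other than age in FBN aorta arrays and 6- and 15-month FBN mesenteric arrays.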

How the results depend on the processing

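Chosen only after the data were seen were the poly-A spike-in and brown adipocyte covariates, the fit of each strain and vessel alone, the exchanged labels, and all values of the 3 added comparisons. Counts below are called probe sets, and unless construction is named the cause was not tested. Of 375 named genes 0 reversed under any alternative fixed in advance. In the brown adipocyte fit 1 of 157 did, Acta2 in the aorta strain difference (-0.03), since that covariate removes what follows adipose signal. Calls ended for 12 of 375 with an offset, 7 without trend and robust estimates, 17 of 371 with quantile normalization, 42 of 375 without a filter, 2 of 217 with the stricter filter, 13 of 375 with array weights, 41 of 333 in 1 fit of all arrays, 32 of 333 with tissue mass, 49 of 375 with poly-A signal, 10 of 157 with the brown adipocyte score and 35 of 139 in a fit of the strain and vessel alone.

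Most counts stayed within 1.5 times under quantile normalization, an offset, plain eBayes and no filter (20, 20, 20 and 19 of 22). The aorta strain by age count of 5 became 0 with quantile normalization, 2 with the offset, 1 without a filter and 1 with plain eBayes. The FBN mesenteric 15 against 6 month count of 2 became 6, 0, 0 and 0. Without a filter, where 31042 probe sets are tested, BN mesenteric 15 against 6 months fell from 583 to 377. The stricter filter tests 8968 probe sets, and most counts fell. BN aorta gave 53 at 15 against 6 and 13 at 24 against 15 months, FBN aorta 7 at 24 against 15, the strain difference in aorta 6140 and strain by age 3. Mesenteric arrays labelled BN gave 208 at 24 against 6 and 1716 at 24 against 15, those labelled FBN 491 at 24 against 15. The mesenteric strain difference gave 162 as labelled and 695 at 6 and 15 months, strain by age 993, and the vessel difference 7780. The FBN mesenteric 15 against 6 month count rose from 2 to 11.

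Array weights raised most counts. BN aorta gave 1461 at 24 against 6, 708 at 15 against 6 and 481 at 24 against 15 months, FBN aorta 438, 86 and 365, strain by age 91, and the age change over strains 1579. Mesenteric arrays labelled BN gave 1151, 1830 and 4168, those labelled FBN 8 at 15 against 6 and 1550 at 24 against 15. The mesenteric strain difference gave 605 as labelled and 2038 at 6 and 15 months, vessel by age 569 and vessel by strain 11176. In 1 fit of all arrays, which shares 1 spread between vessels, BN aorta gave 486, 269 and 154, FBN aorta 437 at 24 against 6 and 12 at 15 against 6, strain by age 21 and the age change over strains 1572. Mesenteric arrays labelled BN gave 267, 243 and 1490, those labelled FBN 1500, 14 and 303, the strain difference 179 as labelled and 767 at 6 and 15 months, strain by age 932 and the age change over strains 383.

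With tissue mass BN aorta gave 456, 233 and 107, FBN aorta 507 at 24 against 6 and 61 at 24 against 15, the strain difference in aorta 3513, strain by age 3 and the age change over strains 1613. Mesenteric BN at 15 against 6 months gave 124, arrays labelled FBN 1587 at 24 against 6 and 0 at 15 against 6, and the age change over strains 629. With poly-A signal BN aorta gave 20 and FBN aorta 1 at 24 against 15, the strain difference in aorta 3299 and strain by age 0. Mesenteric arrays labelled FBN gave 10 at 15 against 6 and 2627 at 24 against 15, the mesenteric age change over strains 1669 and vessel by age 376. With the brown adipocyte score BN aorta gave 1023, 599 and 302, FBN aorta 930, 46 and 262, the strain difference 2251, strain by age 60 and the age change over strains 2075. Fitted alone, BN aorta gave 1305, 446 and 274, FBN aorta 23, 0 and 2, BN mesenteric at 15 against 6 months 969, and FBN mesenteric 4 at 15 against 6 and 454 at 24 against 15. The SD within groups, as a median over probe sets, was 0.25 in BN and 0.384 in FBN aorta, and 0.234 and 0.265 in mesenteric artery. With exchanged labels the mesenteric counts were 1133 for BN at 24 against 15, 1146 for FBN at 24 against 6 and 70 at 24 against 15 months, 1912 for the strain difference and 632 for strain by age. Over the 19 planned comparisons camera called 126 lists and 5 with an estimated correlation, while fry called 85 and all probe sets of the genes 134.

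Leaving out each array in turn, no named gene reversed, and 876 of 14813 gene calls ended. Counts ranged from 106 to 245 for BN aorta at 24 against 6 months, 63 to 141 at 15 against 6 and 19 to 56 at 24 against 15. FBN aorta ranged from 98 to 479, 0 to 10 and 16 to 50. Mesenteric arrays labelled BN ranged from 334 to 641, 232 to 876 and 1888 to 3138, and those labelled FBN from 1952 to 3131, 0 to 33 and 503 to 1021. The strain difference ranged from 9047 to 10491 in aorta and from 287 to 406 in mesenteric artery, 1027 to 1429 at 6 and 15 months. Strain by age ranged from 0 to 12 and from 1192 to 2056, the age change over strains from 548 to 1280 and from 742 to 1188, the vessel difference from 13904 to 14057, vessel by age from 142 to 301 and vessel by strain from 6270 to 8144.

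Arrays that moved a count by over 1.5 times were these. BN aorta at 24 against 6 months gave 111, 131, 112 and 131 without 24-month arrays 1 to 4, and 137, 139, 119, 111 and 106 without 6-month arrays 1, 2, 3, 5 and 6. At 15 against 6 it gave 63 and 65 without 15-month arrays 4 and 5, and 63 without 6-month array 4. At 24 against 15 it gave 19 without 15-month array 5, and 24, 25 and 19 without 24-month arrays 1, 3 and 4. FBN aorta at 24 against 6 gave 479, 98, 102, 119 and 105 without 24-month arrays 1, 2, 3, 5 and 6, and 108 and 105 without 6-month arrays 1 and 2. At 24 against 15 it gave 23, 18 and 19 without 15-month arrays 3, 5 and 6, and 16 without 24-month array 3. BN mesenteric at 15 against 6 gave 315, 278 and 384 without 15-month arrays 1, 5 and 6, 376, 232 and 382 without 6-month arrays 2, 5 and 6, and 876 without FBN 6-month array 2. Arrays labelled FBN at 24 against 15 gave 503 without 24-month array 5. Without FBN aorta 24-month array 1 the aorta age change over strains gave 1280 and vessel by age 301, and vessel by age gave 286 without FBN aorta 6-month array 5. The 3 counts of 5 or fewer moved without 8 arrays (FBN aorta 15 against 6), 25 (FBN mesenteric 15 against 6) and 31 (aorta strain by age).

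Signal over background limits what can be seen, since probe sets with a mean signal below 292.4 in both vessels were left out. Those that reached it in 1 vessel were tested in both, so weaker signals within a group were tested too, such as Inhbb at 30.2, and without an offset the size of their changes depends on background. No paired analysis was possible because the labels do not tie the vessels or arrays of one rat together.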

Other observations

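Chosen only after the result was seen were the comparison averaged over strains and the test of Cpeb1 at 15 months in BN mesenteric artery.

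Over both strains, the imprinted gene Nnat rose by 2.26 ± 0.21 in aorta (n = 12 at each age, adjusted p = 2.82e-08), and its age change differed between vessels by 2.63 ± 0.38 (adjusted p = 1.41e-05). Cpeb1 rose in each strain's aorta, and in mesenteric arrays over both strains. At 15 months it had passed in BN aorta (1.05 ± 0.24) and had gone up in FBN mesenteric artery (1.19 ± 0.22, adjusted p = 0.0441) and down in BN mesenteric artery (-0.80, adjusted p = 0.0369). The calls in BN aorta and FBN mesenteric artery ended under at least 1 alternative, no alternative was run for that in BN mesenteric artery, and chance could not be excluded for FBN mesenteric artery at that age.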
